A study of Mus musculus with 8 samples.

How the data were processed

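RNA of dissected mouse hearts was measured on 8 Affymetrix arrays, 2 for each of WT, Tg-Sirt1, Tg-PPARα and Tg-PPARα/Tg-Sirt1. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridized. The authors processed the arrays with RMA, and the deposited values are log2 expression, 45101 probe sets per array. MAS5 is named in the labels too, with no role stated, and no software versions are given. The values ran from 3.67 to 15.3, array medians from 6.23 to 6.29, and the sorted values of an array departed from their mean over arrays by at most 0.0942, so no further normalization was applied.

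Probe sets were assigned to genes by the array annotation: 34958 carried 1 gene symbol, 932 several and 9211 none. Entrez IDs linked 34754 of the first kind to a RefSeq gene table (mouse assembly GRCm38.p6), which changed 0 symbols. For each of 18194 genes the probe set with the highest mean log2 value was used, and a gene was tested if at least 2 arrays exceeded 6.26, the median of the table, which left 12272 genes. Probe sets whose design lets them read related transcripts were not used as examples in the text, and neither were genes with another probe set called in the opposite direction.

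The model was fitted in R 4.3.3 with limma 3.58.1 as 4 group means over all 8 arrays (lmFit and eBayes, 4 residual degrees of freedom, 7.86 after moderation). The comparisons were each transgenic group against WT, both transgenes against each single one, the single ones against each other, and the interaction, which is both transgenes minus the sum of the single changes. A gene was called at a Benjamini-Hochberg false discovery rate (FDR) under 0.05. No fold is given where a compared group's mean lies below 6.26: the table holds no detection calls, so the log2 change there may be a lower bound. Errors given with ± are standard errors of limma unless marked SD. With groups of 2, leaving out an array leaves 1 array in its group, which is then assumed to vary like the other groups. Tested on simulated data, with 200 of 12272 genes changed in 10 runs for Tg-Sirt1 against WT, the test recovered 61.3% of 1.5-fold, 98.1% of 2-fold and 100% of 4-fold changes, and 99.7% of 4-fold interactions, with 5.98% false calls and 0 with the wrong sign.

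The 44 gene lists held 1046 entries for 897 genes, 140 of them in more than 1 list. A probe set of a single gene was lacking for 89 entries (81 genes, such as Acox1, Acsl1 and Cpt1b), which were left out. The list of the transgenes' own genes was too short to test. The other 43 lists covered lipid and energy use (nuclear receptors and coactivators, PPARα targets, fatty acid oxidation, triglyceride storage, ERR targets, TCA cycle, respiratory complexes I, II and III, and IV, ATP synthase, mitochondrial dynamics and biogenesis, glucose uptake and glycolysis, branched-chain amino acid and ketone use). They covered heart muscle (sarcomere, calcium handling, ion channels, hypertrophy and fetal genes, matrix and fibrosis) and markers of fibroblasts, endothelium, smooth muscle, macrophages, lymphocytes and granulocytes, red cells, adipocytes, atria, ventricles, skeletal muscle, nerve and epicardium. The rest were stress and control lists (unfolded protein response, mitochondrial stress response, antioxidant defence, heat shock, apoptosis, autophagy, ubiquitin ligases, sirtuins and NAD, circadian clock, interferon, cell cycle, ribosomal proteins and sex-linked genes). Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 43 lists of a comparison, and camera gave each list p unless another tool is named. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, one way. A list of 30 genes shifted by 0.3 was found in 10 of 10 simulated runs, in 9 with an estimated correlation, and 1 of 400 unchanged lists was called. In the measured data 0 list calls held with an estimated correlation, so these runs do not vouch for them.

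Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Ppara, Sirt1, Esrra, Esrrb, Esrrg and Ppargc1a, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap (for the interaction, among all called genes), and up to 4 members of each described list by smallest adjusted p. Unless stated, each gene named as changed kept its call when any 1 of the 8 arrays was left out. Calls against WT were compared between groups by counts and covariances, with 100 simulations of unchanged groups that share controls. Other alternatives were quantile normalization, median centring, no filter or a filter on the mean, the mean of all probe sets of a gene, every probe set by itself, a trended and robust variance model, array weights, a fit of the compared groups alone, and the replicate number as a block. Random draws used 10000 lists, 10000 bootstrap samples with 95% intervals, and 1000 shuffles. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.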

Results

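Gene expression was measured in mouse hearts on Affymetrix arrays, which read messenger RNA by hybridization to probe sets. The 8 arrays formed 4 groups of 2 arrays each: wild type (WT), hearts with a cardiac transgene for Sirt1 (Tg-Sirt1), hearts with a cardiac transgene for PPARα (Tg-PPARα), and hearts with both (Tg-PPARα/Tg-Sirt1). Sirt1 is a protein deacetylase that uses NAD, and PPARα is a nuclear receptor that switches on genes of fatty acid use. All mice were males of FVB, an inbred laboratory strain, aged 10 to 11 weeks. The deposited table gave log2 expression (RMA) on each array, and 12272 genes passed the filter and were tested. The labels name no separate animals, so the p-values measure only the spread between these samples.

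The design asks what each transgene changed alone, what both changed together, what each added to the other, and where the joint change departed from the sum of the single ones. Expression correlated across genes at r = 0.989 to r = 0.994 between the arrays of a group; genes are not independent replicates. The first principal component (54.5% of the variance) placed WT at -31.4 and -31.4 and Tg-PPARα/Tg-Sirt1 at 29.6 and 35.3.

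The transgenes themselves could not be checked. Ppara read 11.64 ± 0.07 (log2, SD, n = 2) in WT and 11.20 ± 0.24 in arrays labelled Tg-PPARα, a log2 change of -0.44 ± 0.17 (adjusted p = 0.117). With both transgenes Ppara fell by 1.33 (SE 0.17, adjusted p = 8.16e-04). Its other probe sets fell in Tg-PPARα, with log2 changes of -0.93 and -0.80, and with both transgenes, with -1.51 and -1.52. Sirt1 read 8.17 ± 0.24 in WT and 7.99 ± 0.16 in arrays labelled Tg-Sirt1, a log2 change of -0.18 ± 0.16 (adjusted p = 0.543). With both transgenes Sirt1 fell (log2 change -0.69 ± 0.16, adjusted p = 0.0131). This call ended without WT replicate 2 (adjusted p = 0.0863) and without Tg-PPARα/Tg-Sirt1 replicate 1 (0.0577) or 2 (0.0665). Where these probe sets lie relative to the transgenes is not given, so the levels check neither label. The second Tg-Sirt1 array is titled Tg-Sirt2, while its description and source name Sirt1, and it was placed by these. Across genes it correlated best with the first Tg-Sirt1 array (r = 0.989). Group names stand for arrays so labelled.

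Tg-PPARα against WT asked what the PPARα transgene changed alone (n = 2 arrays per group, ± SE). Acaa1b, a peroxisomal thiolase of fatty acid oxidation, rose (log2 change 5.64 ± 0.26, adjusted p = 1.73e-05). Mttp, which loads triglyceride onto lipoproteins, rose 13.0-fold (adjusted p = 9.34e-06). The tight junction gene Cldn23 rose (log2 change 5.20 ± 0.35, adjusted p = 1.31e-04) and the elastase gene Cela1 (log2 change 4.27 ± 0.10, adjusted p = 1.98e-06). Mmp12, a metalloelastase of macrophages, rose (log2 change 4.08 ± 0.20, adjusted p = 2.57e-05). The proton channel gene Otop1 rose by a log2 change of 3.64 ± 0.15. Casq1, the calcium-binding calsequestrin of skeletal muscle, fell 16.1-fold (log2 change -4.01 ± 0.15, adjusted p = 9.34e-06). Rpl3l, a striated muscle form of a ribosomal protein, fell 15.1-fold (log2 change -3.92 ± 0.29, adjusted p = 2.20e-04). The carbonic anhydrase gene Car3 fell by a log2 change of -3.92 ± 0.43, the triglyceride hydrolase gene Ces1d by -3.89 ± 0.14 and the secreted protein gene Lgi1 by -3.83 ± 0.18. Ppargc1a, a coactivator of mitochondrial genes, fell 1.45-fold (log2 change -0.54 ± 0.14, adjusted p = 0.0406). That call ended without WT replicate 1 (adjusted p = 0.134) or 2 (0.149), without Tg-PPARα replicate 1 (0.196) or 2 (0.0656), with quantile normalization (0.0504) and with no filter (0.0526). The estrogen-related receptor genes, whose products drive energy metabolism, did not pass: Esrra (-0.15 ± 0.09, adjusted p = 0.315), Esrrb (-0.37 ± 0.13, adjusted p = 0.0897) and Esrrg (-0.09 ± 0.09, adjusted p = 0.546).

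Among the lists of genes for lipid use, PPARα targets went both ways in Tg-PPARα and did not pass (adjusted p = 0.107). Of 45 genes 13 rose and 6 fell (14 and 10 adjusted over the list alone). Plin2, which coats lipid droplets, rose (log2 change 1.38 ± 0.15), as did Cidea, which enlarges them (1.35 ± 0.15), while the retinol saturase gene Retsat fell (-1.03 ± 0.11). Fatty acid oxidation enzymes had a median of -0.02 and a mean of 0.01 (adjusted p = 0.693). Of 20 genes 3 rose and 2 fell (3 and 4 adjusted over the list alone). Triglyceride genes were also split (adjusted p = 0.481). Of 22 genes 5 rose and 5 fell (5 and 8 adjusted over the list alone), and the droplet coat gene Plin3 was lower (-1.67 ± 0.11). The list of nuclear receptors and coactivators fell (adjusted p = 0.0197, adjusted p = 0.699 with an estimated correlation). Of 18 genes 0 rose and 4 fell (0 and 6 adjusted over the list alone). Genes of respiratory complex I, which passes on electrons from NADH, fell as a list (median log2 -0.20, adjusted p = 3.89e-05, adjusted p = 0.699 with an estimated correlation). Of 33 genes 0 rose and 3 fell (0 and 9 adjusted over the list alone). The targets of estrogen-related receptors (ERR) fell as a list (adjusted p = 0.00736, adjusted p = 0.705 with an estimated correlation). Of 65 genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), and Got1, of the malate-aspartate shuttle, was lower (-0.62 ± 0.10). Respiratory complexes II and III fell (adjusted p = 0.0432, adjusted p = 0.705 with an estimated correlation). Of 14 genes 0 rose and 1 fell (0 and 1 adjusted over the list alone). The list of sirtuins and NAD metabolism fell (adjusted p = 0.0376, adjusted p = 0.699 with an estimated correlation). Of 17 genes 0 rose and 4 fell (0 and 5 adjusted over the list alone), among them Naprt, which makes NAD from nicotinic acid (-0.72 ± 0.10).

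In Tg-PPARα ion channel genes, which set the heart's rhythm and repolarization, fell (median log2 -0.45, adjusted p = 1.47e-05, adjusted p = 0.242 with an estimated correlation). Of 20 genes 1 rose and 10 fell (1 and 14 adjusted over the list alone). The potassium channel gene Kcnj5 (-1.63 ± 0.14) and the calcium channel gene Cacna1g (-1.83 ± 0.21) fell, while the sodium channel subunit gene Scn4b rose (0.82 ± 0.13). Hypertrophy and fetal genes rose (adjusted p = 0.0197, adjusted p = 0.705 with an estimated correlation). Of 28 genes 7 rose and 1 fell (7 and 1 adjusted over the list alone). The natriuretic peptide gene Nppa (1.86 ± 0.25) and the calcineurin regulator gene Rcan1 (0.99 ± 0.15) were higher and the muscle gene Fhl2 lower (-0.70 ± 0.08). Extracellular matrix genes rose (median log2 0.68, adjusted p = 9.14e-09, adjusted p = 0.699 with an estimated correlation). Of 44 genes 17 rose and 0 fell (29 and 0 adjusted over the list alone), with thrombospondin 4, Thbs4 (1.79 ± 0.16), and the growth factor gene Tgfb2 (2.38 ± 0.35) among them. Markers of fibroblasts rose with the matrix genes (median log2 0.31, adjusted p = 0.0128, adjusted p = 0.699 with an estimated correlation). Of 17 genes 4 rose and 0 fell (9 and 1 adjusted over the list alone). Endothelial markers were lower as a list (median log2 -0.21, adjusted p = 0.0408, adjusted p = 0.699 with an estimated correlation). Of 19 genes 0 passed, also adjusted over the list alone. Macrophage markers were lower as a list (median log2 -0.36, adjusted p = 0.0408, adjusted p = 0.705 with an estimated correlation). Of 24 genes 2 rose and 7 fell (2 and 10 adjusted over the list alone). The complement gene C1qa fell (-1.19 ± 0.15) and the integrin gene Itgax rose (1.02 ± 0.09). Atrial markers rose (adjusted p = 0.0432, adjusted p = 0.699 with an estimated correlation). Of 11 genes 3 rose and 0 fell (6 and 0 adjusted over the list alone). Antioxidant genes rose as a list (adjusted p = 0.0408, adjusted p = 0.699 with an estimated correlation). Of 30 genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the glutathione synthetase gene Gss at 0.56 ± 0.09.

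Leaving out WT replicate 1 ended the list calls of ERR targets (adjusted p = 0.0652), complexes II and III (0.119), hypertrophy genes (0.0528), endothelial markers (0.0528), macrophage markers (0.0668), atrial markers (0.0668), antioxidant genes (0.136) and NAD genes (0.114). Calls of complexes II and III (adjusted p = 0.0701), endothelial markers (0.136) and macrophage markers (0.0571) ended without Tg-PPARα replicate 1. Without Tg-PPARα replicate 2, the list calls of complexes II and III (adjusted p = 0.109), fibroblast markers (0.0774), atrial markers (0.0968) and antioxidant genes (0.101) ended. Leaving out Tg-PPARα/Tg-Sirt1 replicate 1 or 2 ended the list call of complexes II and III (adjusted p = 0.0637). Calls of endothelial markers (adjusted p = 0.0875) and atrial markers (0.0919) ended without WT replicate 2. Without Tg-Sirt1 replicate 1 or 2, the list call of macrophage markers (adjusted p = 0.0778) ended. Settings other than fry also ended the calls of complexes II and III and of endothelial, atrial and macrophage markers. Of 12272 genes, 1943 passed FDR 0.05 in limma for Tg-PPARα against WT, 885 higher and 1058 lower, and 409 of them changed at least 2-fold (233 higher, 176 lower). The share of higher genes was 45.5%, but 52.6% after quantile normalization, 57.5% without WT replicate 2 and 56.6% without Tg-PPARα replicate 1. Camera called 13 of 43 lists, 5 up and 8 down, against 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 11 by fry. Fry kept 4 of the 13, nuclear receptors, complex I, ion channels and NAD genes. The gene count was 1043 without WT replicate 1, 815 without WT replicate 2, 924 without Tg-PPARα replicate 1 and 969 without Tg-PPARα replicate 2. In each of the fits that left out an array of these groups, 628 genes passed.

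**Figure D1:**
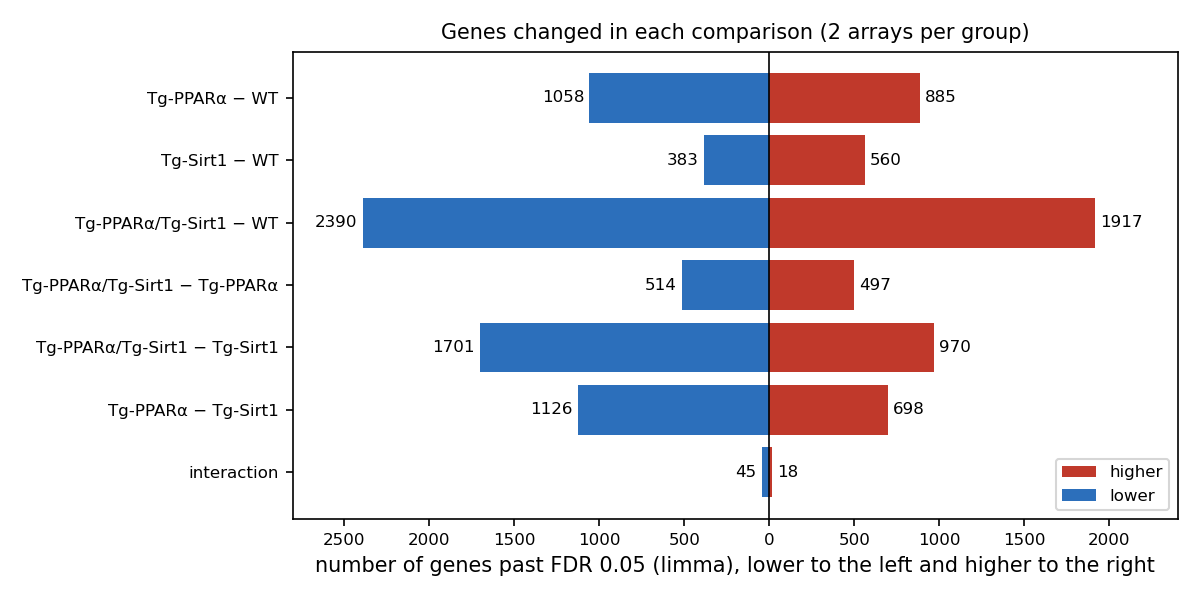
Number of genes past FDR 0.05 in limma (horizontal axis, lower genes to the left and higher genes to the right) in each of the 7 comparisons, with 2 arrays per group. Tg-PPARα/Tg-Sirt1 against WT had the most, 1917 higher and 2390 lower, and the interaction 18 higher and 45 lower.

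Tg-Sirt1 against WT asked what the Sirt1 transgene changed alone (n = 2 arrays per group, ± SE). Acta1, skeletal α-actin, fell 31.9-fold (log2 change -4.99 ± 0.35, adjusted p = 2.52e-04), from a log2 level of 14.73 ± 0.03 (SD) in WT to 9.74 ± 0.95. Ces1d fell 13.2-fold (log2 change -3.72 ± 0.14, adjusted p = 3.44e-05). Casq1 fell by a log2 change of -2.78 ± 0.15, the ephrin gene Efnb3 by -2.32 ± 0.29 and Gm19277 by -2.49 ± 0.14. Bex1, an adaptor protein gene of neurons and regenerating muscle, rose 38.8-fold (log2 change 5.28 ± 0.33, adjusted p = 1.74e-04). The slow skeletal troponin gene Tnnt1 rose 20.6-fold (log2 change 4.36 ± 0.23, adjusted p = 1.06e-04), and Clca4a, a chloride channel regulator gene, rose (log2 change 4.53 ± 0.29, adjusted p = 1.74e-04). The endoribonuclease gene Endou rose by a log2 change of 4.17 ± 0.26, the cation exchanger gene Slc24a2 by 4.12 ± 0.13, the prostaglandin F receptor gene Ptgfr by 3.76 ± 0.16, the tubulin gene Tubb2b by 3.57 ± 0.36 and the serine protease gene Tmprss4 by 3.49 ± 0.22. Ppargc1a (0.16 ± 0.14, adjusted p = 0.547), Ppara (-0.48 ± 0.17, adjusted p = 0.130), Esrra (-0.10 ± 0.09, adjusted p = 0.573), Esrrb (-0.01 ± 0.13, adjusted p = 0.974) and Esrrg (0.03 ± 0.09, adjusted p = 0.873) did not pass. The sign for Esrrb turned with median centring (0.0053), and that for Esrrg with quantile normalization (-0.0077).

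PPARα targets fell in Tg-Sirt1 (median log2 -0.39, adjusted p = 5.42e-11, or 0.655 with an estimated correlation). Of 45 genes 0 rose and 16 fell (0 and 24 adjusted over the list alone). Dgat2, which makes triglyceride (log2 change -1.20 ± 0.09), Pdk4, which turns off glucose oxidation (-1.98 ± 0.25), and Cpt2, of the mitochondrial carnitine shuttle (-0.89 ± 0.13), fell. The call of Cpt2 ended without WT replicate 2 (adjusted p = 0.0537). Fatty acid oxidation enzymes fell (median log2 -0.29, adjusted p = 1.10e-06, or 0.725 with an estimated correlation). Of 20 genes 0 rose and 7 fell (0 and 10 adjusted over the list alone). Triglyceride genes fell (median log2 -0.24, adjusted p = 8.62e-04, or 0.725 with an estimated correlation). Of 22 genes 1 rose and 6 fell (1 and 11 adjusted over the list alone), with Plin3 at -0.93 ± 0.11. PPARα targets shared 17 genes with the 20 oxidation enzymes and 8 with the 22 triglyceride genes, so these lists are not independent. ERR targets fell as a list (median log2 -0.09, adjusted p = 7.62e-04, adjusted p = 0.808 with an estimated correlation). Of 65 genes 1 rose and 2 fell (0 and 0 adjusted over the list alone). Complex I fell as a list (median log2 -0.11, adjusted p = 0.00214, adjusted p = 0.808 with an estimated correlation). Of 33 genes 0 rose and 1 fell (0 and 0 adjusted over the list alone). Fbp2, the muscle enzyme that reverses a step of glycolysis, fell (-1.94 ± 0.13).

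Matrix genes rose in Tg-Sirt1 (median log2 0.65, array medians 0.33 and 0.95, adjusted p = 1.73e-09, or 0.725 with an estimated correlation). Of 44 genes 4 rose and 0 fell (19 and 0 adjusted over the list alone), with Thbs4 at 2.87 ± 0.16. Fibroblast markers rose (median log2 0.36, adjusted p = 7.62e-04, or 0.742 with an estimated correlation). Of 17 genes 4 rose and 0 fell (6 and 0 adjusted over the list alone). Cell cycle genes rose (median log2 0.52, adjusted p = 1.11e-04, or 0.769 with an estimated correlation). Of 17 genes 5 rose and 0 fell (10 and 0 adjusted over the list alone). In these lists, calls of Tgfb2, Col14a1, Col1a1, Meox1, Pcolce, Vim, Ccnb2, Ccnd1, Ccnd2 and Mki67 each ended in some fits without 1 array. Endothelial markers (median log2 -0.11, adjusted p = 0.116) and macrophage markers (0.994) did not pass. The list of skeletal muscle markers fell (adjusted p = 7.62e-04, or 0.655 with an estimated correlation). Of 10 genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with Acta1, Casq1 and the myosin-binding protein gene Mybpc2 (-1.39 ± 0.17) lower and the myosin light chain gene Myl1 higher (0.86 ± 0.12). Hypertrophy and fetal genes did not pass as a list (adjusted p = 0.164), with array medians of -0.18 and 0.88 relative to WT. Rcan1 rose (1.05 ± 0.15), while the channel subunit gene Kcnip2 fell (-0.70 ± 0.09). Leaving out Tg-Sirt1 replicate 2 ended the list calls of ERR targets (adjusted p = 0.161) and complex I (0.142).

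In limma, 943 genes passed for Tg-Sirt1 against WT, 560 higher (59.4%, but 48.9% without WT replicate 1) and 383 lower, and 214 changed at least 2-fold (144 higher, 70 lower). Camera called 9 lists, 3 up and 6 down, against 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 3 by fry. Of the 9, fry kept 2, PPARα targets and skeletal muscle markers. The gene count was 327 without WT replicate 1, 357 without WT replicate 2 and 398 without Tg-Sirt1 replicate 2, and 519 in a fit of the WT and Tg-Sirt1 arrays alone. Of the 943 genes, 233 passed in each fit that left out an array of these groups.

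Hearts with both transgenes, compared with WT, showed what the pair changed together (n = 2 arrays per group, ± SE). Tnni1, the slow troponin I of fetal heart, rose (log2 change 6.04 ± 0.22, adjusted p = 5.73e-06). Cldn23 rose (log2 change 5.66 ± 0.35, adjusted p = 4.53e-05) and Bex1 rose 42.5-fold (log2 change 5.41 ± 0.33, adjusted p = 4.31e-05). Sarcolipin, Sln, an inhibitor of the calcium pump, rose 33.2-fold (log2 change 5.05 ± 0.71, adjusted p = 0.00139). Tubb2b, the glutamate transporter gene Slc1a1 and Mttp rose by log2 changes of 4.82 ± 0.36, 4.63 ± 0.35 and 4.28 ± 0.13. Ces1d fell 38.1-fold (log2 change -5.25 ± 0.14, adjusted p = 2.33e-06) and Casq1 28.2-fold (log2 change -4.82 ± 0.15, adjusted p = 3.33e-06). The amino acid transporter gene Slc36a2 fell by a log2 change of -4.20 ± 0.16 and Lgi1 by -3.84 ± 0.18. Ppargc1a fell 2.25-fold (log2 change -1.17 ± 0.14, adjusted p = 7.76e-04), Esrra 1.36-fold (log2 change -0.44 ± 0.09, adjusted p = 0.00762) and Esrrb 1.59-fold (log2 change -0.67 ± 0.13, adjusted p = 0.00521). Esrrg did not pass (log2 change -0.08 ± 0.09, adjusted p = 0.517).

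In hearts with both transgenes complex I genes fell (median log2 -0.36, adjusted p = 1.20e-06, or 0.693 with an estimated correlation). Of 33 genes 0 rose and 21 fell (0 and 27 adjusted over the list alone), with Ndufs4 (-0.72 ± 0.11), Ndufa6 (-0.61 ± 0.10) and Ndufs7 (-0.59 ± 0.10) as examples. Endothelial markers fell by a like amount (median log2 -0.33, adjusted p = 0.0140, or 0.693 with an estimated correlation). Of 19 genes 0 rose and 7 fell (0 and 8 adjusted over the list alone). ERR targets fell (median log2 -0.21, adjusted p = 9.67e-05, or 0.693 with an estimated correlation). Of 65 genes 1 rose and 25 fell (1 and 25 adjusted over the list alone), among them Perm1, a muscle regulator of mitochondrial genes (-1.27 ± 0.10), the cytochrome oxidase subunit gene Cox7a1 (-0.93 ± 0.10) and Got1 (-0.78 ± 0.10). This list shares 19 genes with the TCA cycle list, 8 with complex I and 4 with PPARα targets. TCA cycle genes fell as a list (median log2 -0.24, adjusted p = 0.0201, or 0.693 with an estimated correlation). Of 25 genes 1 rose and 10 fell (1 and 10 adjusted over the list alone). Complexes II and III fell (median log2 -0.23, adjusted p = 0.0429, adjusted p = 0.693 with an estimated correlation). Of 14 genes 0 rose and 5 fell (0 and 5 adjusted over the list alone). Complex IV did not pass (adjusted p = 0.270). Of 19 genes 2 rose and 6 fell (2 and 6 adjusted over the list alone). ATP synthase did not pass (adjusted p = 0.101). Of 17 genes 1 rose and 6 fell (1 and 6 adjusted over the list alone). Genes of mitochondrial dynamics and biogenesis did not pass (adjusted p = 0.0528). Of 28 genes 2 rose and 9 fell (3 and 10 adjusted over the list alone).

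Branched-chain amino acid and ketone genes fell with both transgenes (median log2 -0.34, adjusted p = 0.00222, adjusted p = 0.693 with an estimated correlation). Of 18 genes 0 rose and 9 fell (0 and 10 adjusted over the list alone), with the ketone enzyme gene Bdh1 at -2.40 ± 0.18. Nuclear receptors and coactivators fell (median log2 -0.37, adjusted p = 0.0201, adjusted p = 0.693 with an estimated correlation). Of 18 genes 0 rose and 9 fell (0 and 10 adjusted over the list alone), among them Rxra, the partner of PPARα (-0.98 ± 0.09). Sirtuin and NAD genes fell (median log2 -0.32, adjusted p = 0.0137, adjusted p = 0.693 with an estimated correlation). Of 17 genes 0 rose and 9 fell (0 and 10 adjusted over the list alone), with Nampt, which recycles NAD, at -1.38 ± 0.12 and the mitochondrial deacetylase gene Sirt3 at -0.81 ± 0.14. PPARα targets did not pass with both transgenes (adjusted p = 0.639). Of 45 genes 8 rose and 14 fell (8 and 15 adjusted over the list alone), with Dgat2 (-1.81 ± 0.09) and Retsat (-1.69 ± 0.11) lower and Plin2 higher (1.97 ± 0.15). Oxidation enzymes did not pass (adjusted p = 0.292). Of 20 genes 2 rose and 7 fell (2 and 8 adjusted over the list alone), with Cpt2 at -1.14 ± 0.13. Triglyceride genes did not pass (adjusted p = 0.109). Of 22 genes 5 rose and 11 fell (5 and 13 adjusted over the list alone), with Plin3 lower (-2.09 ± 0.11). Genes of glucose uptake and glycolysis did not pass (adjusted p = 0.141). Of 30 genes 5 rose and 14 fell (5 and 14 adjusted over the list alone), with the insulin-regulated transporter gene Slc2a4 lower (-1.32 ± 0.13). Calls of TCA cycle genes (adjusted p = 0.113) and complexes II and III (0.0942) ended without WT replicate 1. Without Tg-PPARα replicate 1 or 2, the list call of complexes II and III (adjusted p = 0.0591) ended. Leaving out Tg-PPARα/Tg-Sirt1 replicate 1 ended the list call of complexes II and III (adjusted p = 0.0676). The list call of complexes II and III (adjusted p = 0.0939) ended without Tg-PPARα/Tg-Sirt1 replicate 2. Complexes II and III also lost the call with quantile normalization (adjusted p = 0.109) and in a fit of the compared groups alone (0.0549).

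Ion channel genes fell with both transgenes (median log2 -0.59, adjusted p = 1.55e-04, or 0.391 with an estimated correlation). Of 20 genes 1 rose and 13 fell (1 and 16 adjusted over the list alone), with Kcnj5 (-2.68 ± 0.14) and Kcnip2, a subunit of the transient outward current (-1.86 ± 0.09), as examples. Calcium genes did not pass (adjusted p = 0.118). Of 23 genes 4 rose and 9 fell (4 and 9 adjusted over the list alone), with Rcan1 higher (2.15 ± 0.15). Sarcomere genes did not pass (adjusted p = 0.614). Of 24 genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with the Z-disc gene Myot lower (-1.91 ± 0.24). Hypertrophy and fetal genes rose (median log2 0.85, adjusted p = 0.00222, or 0.693 with an estimated correlation). Of 28 genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), led by Tnni1 and Rcan1, while Fhl2 was lower (-1.78 ± 0.08). Ventricular (adjusted p = 0.118) and atrial markers (array medians 0.30 and 0.44) did not pass. The share of atrium in the RNA was not tested. Of 8 ventricular genes 0 rose and 3 fell (0 and 3 adjusted over the list alone). The transcription factor gene Irx4 fell (-2.17 ± 0.15). Matrix genes rose (median log2 0.90, adjusted p = 1.73e-09, or 0.693 with an estimated correlation). Of 44 genes 28 rose and 0 fell (30 and 0 adjusted over the list alone), with Tgfb2 (3.42 ± 0.35), the cartilage matrix gene Comp (2.54 ± 0.32) and Thbs4 (2.36 ± 0.16) as examples. Fibroblast markers, 5 of 17 shared with the matrix list, did not pass (median log2 0.21, adjusted p = 0.101). Of 17 genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with Meox1, a transcription factor gene (1.71 ± 0.16), higher and Fap, a surface protease gene, lower (-0.87 ± 0.15). Macrophage markers fell (median log2 -0.61, adjusted p = 0.0140, or 0.693 with an estimated correlation). Of 24 genes 1 rose and 12 fell (1 and 14 adjusted over the list alone), with Cd74, of antigen presentation, at -0.90 ± 0.12. Antioxidant genes rose as a list (median log2 0.28, adjusted p = 0.0345, or 0.693 with an estimated correlation). Of 30 genes 8 rose and 5 fell (13 and 6 adjusted over the list alone), with Gss higher (1.10 ± 0.09). That call ended without WT replicate 1 (adjusted p = 0.0942) and without Tg-PPARα/Tg-Sirt1 replicate 2 (0.0755).

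The test against WT called 4307 genes with both transgenes, 1917 higher (44.5%, but 51.1% without WT replicate 2) and 2390 lower, and 869 changed at least 2-fold (490 higher, 379 lower). Of 43 lists, camera called 13, 3 up and 10 down, against 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 22 by fry. Fry kept 10 of the 13, but not hypertrophy genes (adjusted p = 0.109), macrophage markers (0.110) or antioxidant genes (0.0515). The gene count was 2412 without Tg-PPARα/Tg-Sirt1 replicate 2, and 2099 of the 4307 genes passed in each fit that left out an array of these groups.

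**Figure D2:**
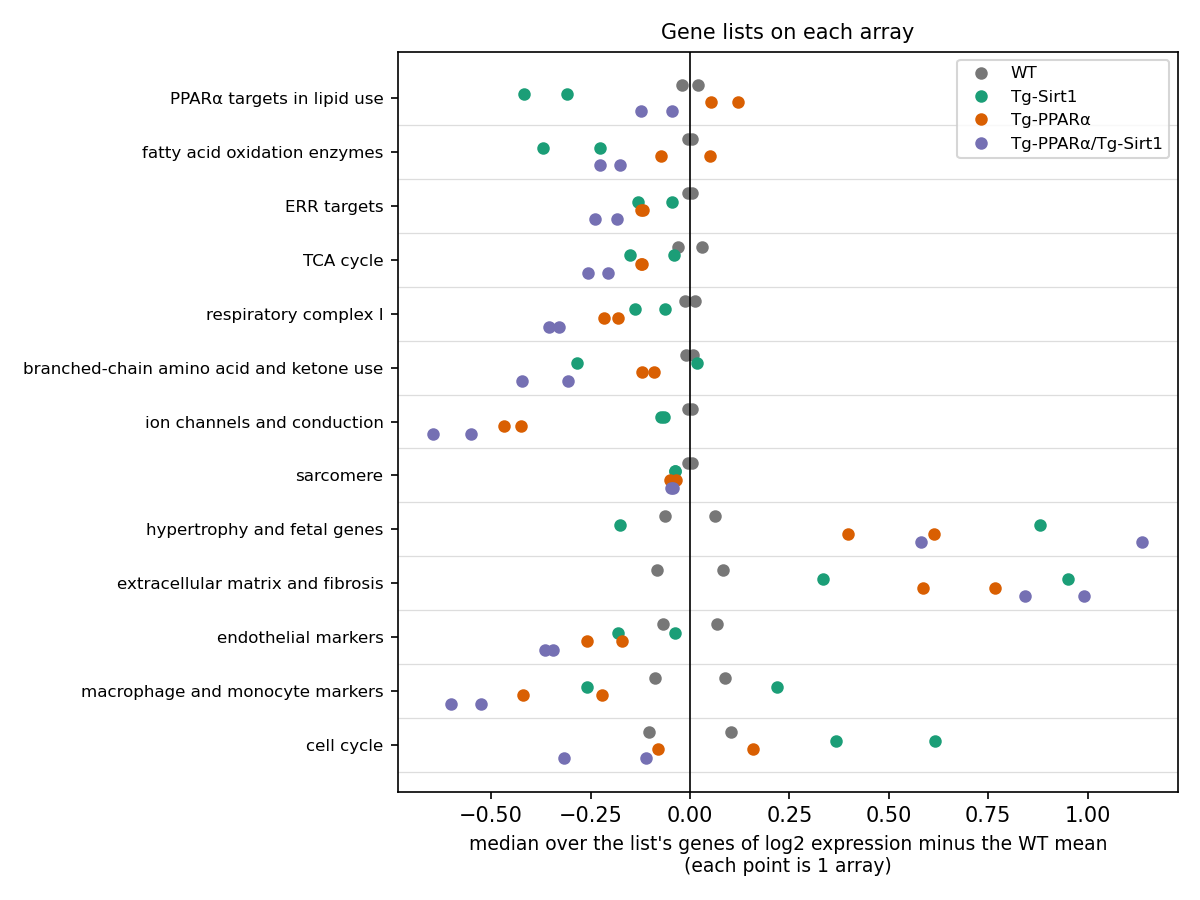
Median over the genes of each list of log2 expression minus the WT mean (horizontal axis), 1 point per array, for 13 lists (vertical axis) and the 4 groups. Ion channel genes lay at -0.55 and -0.65 and matrix genes at 0.99 and 0.84 with both transgenes, and PPARα targets at -0.31 and -0.42 in Tg-Sirt1.

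Calls against WT overlapped. Of the genes called in Tg-PPARα and in Tg-Sirt1, 191 were higher in both and 187 lower in both, where independent calls would give 40.4 and 33.0, and 61 were called in opposite directions. Thbs4 rose in both, and Casq1 and Ces1d fell in both. Tg-PPARα and Tg-PPARα/Tg-Sirt1 shared 725 higher and 922 lower genes (138 and 206 if independent, 21 opposite). Tg-Sirt1 and Tg-PPARα/Tg-Sirt1 shared 403 and 330 (87.5 and 74.6 if independent, 20 opposite). Log2 changes correlated across genes at r = 0.405, 0.811 and 0.646. The pairs share the WT arrays, and 100 simulations of unchanged groups sharing controls gave r near 0.500. Covariances were 0.0637, 0.209 and 0.139 against a simulated 0.010, and the differences (0.0537, 0.199 and 0.129) estimate the part that the shared arrays do not add. Part of the overlap in counts may come from these arrays; the 0 shared calls of the simulations are no baseline for it, since unchanged groups give few calls. The 378 genes that the single transgenes shared in direction became 137 without WT replicate 1, 139 without WT replicate 2, 178 without Tg-Sirt1 replicate 2, 231 without Tg-PPARα replicate 1, 204 without Tg-PPARα replicate 2 and 220 in fits of the compared groups alone. The 1647 that Tg-PPARα shared with both transgenes became 911 without WT replicate 1, 702 without WT replicate 2, 832 without Tg-PPARα replicate 1 and 832 without Tg-PPARα replicate 2. The 733 of Tg-Sirt1 became 274, 288 and 318 without WT replicate 1, WT replicate 2 and Tg-Sirt1 replicate 2, and 419 in fits of the compared groups alone.

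Adding the Sirt1 transgene to the PPARα transgene, compared as Tg-PPARα/Tg-Sirt1 against Tg-PPARα, lowered several genes that Tg-PPARα had raised against WT (n = 2 arrays per group, ± SE). Acaa1b fell (log2 change -4.55 ± 0.26, adjusted p = 2.14e-04) and Mmp12 (log2 change -4.35 ± 0.20, adjusted p = 1.13e-04). Epidermal growth factor, Egf, Cyp2b10, a cytochrome P450, and Acsm5, a fatty acyl-CoA synthetase, fell by log2 changes of -3.29 ± 0.15, -2.54 ± 0.19 and -2.19 ± 0.10. Tubb2b rose (log2 change 4.36 ± 0.36, adjusted p = 7.17e-04) and Tnni1 rose 10.8-fold (log2 change 3.43 ± 0.22, adjusted p = 2.84e-04). Clca4a, Bex4 and the secreted factor gene Ndnf rose by 3.25 ± 0.29, 3.13 ± 0.37 and 2.70 ± 0.18. Ppargc1a fell 1.54-fold (log2 change -0.63 ± 0.14, adjusted p = 0.0396), and Ppara fell 1.86-fold (log2 change -0.89 ± 0.17, adjusted p = 0.0187). The Ppargc1a call ended without either WT array (adjusted p = 0.0700), without Tg-PPARα replicate 1 (0.0856) or 2 (0.154), without Tg-PPARα/Tg-Sirt1 replicate 2 (0.246), with the mean of its probe sets (0.0666) and in a fit of these groups alone (0.0706). That of Ppara ended without Tg-PPARα replicate 1 (0.112), without Tg-PPARα/Tg-Sirt1 replicate 2 (0.110) and in a fit of these groups alone (0.0570). Esrra (-0.29 ± 0.09, adjusted p = 0.0982), Esrrb (-0.30 ± 0.13, adjusted p = 0.204), Sirt1 (-0.33 ± 0.16, adjusted p = 0.267) and Esrrg (0.01 ± 0.09, adjusted p = 0.967) did not pass, and Esrrg turned negative with quantile normalization (-0.014).

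PPARα targets fell in this step (median log2 -0.22, adjusted p = 2.59e-04, adjusted p = 0.855 with an estimated correlation). Of the 45 genes 0 rose and 11 fell (2 and 17 adjusted over the list alone), with Acaa1b and Dgat2 (-1.10 ± 0.09) among the lower. Oxidation enzymes fell as a list (median log2 -0.20, adjusted p = 0.0112, adjusted p = 0.855 with an estimated correlation). Of the 20 genes 0 rose and 2 fell (0 and 3 adjusted over the list alone). Triglyceride genes fell (median log2 -0.16, adjusted p = 0.0282, adjusted p = 0.855 with an estimated correlation). Of the 22 genes 0 rose and 3 fell (2 and 7 adjusted over the list alone). ERR targets fell (median log2 -0.10, adjusted p = 0.00784, adjusted p = 0.855 with an estimated correlation). Of the 65 genes 0 rose and 4 fell (0 and 3 adjusted over the list alone), with Perm1 at -0.88 ± 0.10. Complex I fell as a list (median log2 -0.13, adjusted p = 0.00290, adjusted p = 0.855 with an estimated correlation). Of the 33 genes 0 passed, also adjusted over the list alone. Branched-chain amino acid and ketone genes fell (median log2 -0.25, adjusted p = 0.00290, adjusted p = 0.855 with an estimated correlation). Of the 18 genes 0 rose and 2 fell (0 and 5 adjusted over the list alone), with Bdh1 at -2.05 ± 0.18. Hypertrophy and fetal genes rose (median log2 0.33, adjusted p = 0.0282, adjusted p = 0.858 with an estimated correlation). Of the 28 genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Fhl2 lower (-1.08 ± 0.08). Matrix genes rose as a list (median log2 0.26, adjusted p = 0.00290, adjusted p = 0.855 with an estimated correlation). Of the 44 genes 1 rose and 0 fell (0 and 0 adjusted over the list alone). Beside them macrophage markers (adjusted p = 0.592) and endothelial markers (adjusted p = 0.172) did not pass. Without Tg-PPARα replicate 1, the list calls of oxidation enzymes (adjusted p = 0.142), triglyceride genes (0.0583), ERR targets (0.0583) and hypertrophy genes (0.0550) ended. Leaving out Tg-PPARα/Tg-Sirt1 replicate 2 ended the list calls of triglyceride genes (adjusted p = 0.0851), complex I (0.0528) and hypertrophy genes (0.134). With the mean of all probe sets of a gene, the calls of triglyceride genes (0.0640) and hypertrophy genes (0.0515) ended.

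By limma 1011 genes passed for this step, 497 higher (49.2%, but 59.1% without Tg-PPARα replicate 2) and 514 lower, and 234 changed at least 2-fold (131 higher, 103 lower). Camera called 8 lists, 2 up and 6 down, against 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 4 by fry, which kept 0 of the 8 (adjusted p from 0.0576 for PPARα targets to 0.487 for hypertrophy genes). Gene counts were 286 without Tg-PPARα replicate 1, 435 without Tg-PPARα replicate 2, 450 without Tg-PPARα/Tg-Sirt1 replicate 1 and 222 without Tg-PPARα/Tg-Sirt1 replicate 2, and 188 genes passed in each fit that left out an array of these groups.

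Tg-PPARα/Tg-Sirt1 against Tg-Sirt1 showed what the PPARα transgene added to the Sirt1 transgene (n = 2 arrays per group, ± SE). Tnni1 rose 28.5-fold (log2 change 4.83 ± 0.22, adjusted p = 4.06e-05). Acta1 rose 27.9-fold (log2 change 4.80 ± 0.35, adjusted p = 2.05e-04), to 14.53 ± 0.03 (SD) against 14.73 ± 0.03 in WT. Cldn23 and Mttp rose by log2 changes of 4.07 ± 0.35 and 3.34 ± 0.13. Ptgfr fell 17.1-fold (log2 change -4.09 ± 0.16, adjusted p = 2.20e-05), and Endou and Tnnt1 fell by log2 changes of -3.40 ± 0.26 and -3.37 ± 0.23. Ppargc1a fell 2.51-fold (log2 change -1.33 ± 0.14, adjusted p = 0.00103). Ppara fell (log2 change -0.85 ± 0.17, adjusted p = 0.0109), a call that ended without Tg-PPARα/Tg-Sirt1 replicate 2 (adjusted p = 0.0693). Esrra (log2 change -0.35 ± 0.09) and Esrrb (-0.66 ± 0.13) fell. The Esrra call ended without any 1 of the 6 transgenic arrays, at adjusted p from 0.0522 to 0.145 (without Tg-PPARα/Tg-Sirt1 replicate 2), and in a fit of these groups alone (0.0625). That of Esrrb ended without Tg-PPARα/Tg-Sirt1 replicate 2 (0.0823) and with the mean of its probe sets (0.0512). Sirt1 (-0.50 ± 0.16, adjusted p = 0.0602) and Esrrg (-0.11 ± 0.09, adjusted p = 0.399) did not pass.

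In this step PPARα targets rose (median log2 0.18, adjusted p = 3.93e-04, adjusted p = 0.759 with an estimated correlation). Of the 45 genes 15 rose and 3 fell (16 and 4 adjusted over the list alone), with Plin2 (1.90 ± 0.15) and Cidea (1.62 ± 0.15) higher and Retsat lower (-1.16 ± 0.11). Nuclear receptors and coactivators fell (adjusted p = 0.00623, adjusted p = 0.759 with an estimated correlation). Of the 18 genes 0 rose and 7 fell (0 and 8 adjusted over the list alone). Complex I fell (median log2 -0.21, adjusted p = 1.31e-04, adjusted p = 0.759 with an estimated correlation). Of the 33 genes 0 rose and 9 fell (0 and 9 adjusted over the list alone). ERR targets fell (median log2 -0.13, adjusted p = 0.0192, adjusted p = 0.759 with an estimated correlation). Of the 65 genes 1 rose and 9 fell (1 and 8 adjusted over the list alone), with Perm1 at -1.09 ± 0.10. Mitochondrial dynamics and biogenesis fell (median log2 -0.19, adjusted p = 0.0160, adjusted p = 0.759 with an estimated correlation). Of the 28 genes 0 rose and 7 fell (0 and 7 adjusted over the list alone). Branched-chain amino acid and ketone genes fell (adjusted p = 0.0496, adjusted p = 0.759 with an estimated correlation). Of the 18 genes 0 rose and 6 fell (1 and 8 adjusted over the list alone). Sirtuin and NAD genes fell (adjusted p = 0.0219, adjusted p = 0.759 with an estimated correlation). Of the 17 genes 0 rose and 6 fell (1 and 8 adjusted over the list alone), with Naprt at -0.84 ± 0.10.

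Ion channel genes also fell when the PPARα transgene was added (median log2 -0.65, adjusted p = 2.21e-05, adjusted p = 0.232 with an estimated correlation). Of the 20 genes 0 rose and 12 fell (0 and 15 adjusted over the list alone), with Kcnj5 (-2.00 ± 0.14) and the potassium channel gene Kcnd2 (-2.98 ± 0.36) lower. Hypertrophy and fetal genes rose (median log2 0.38, adjusted p = 0.00247, adjusted p = 0.759 with an estimated correlation). Of the 28 genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). Matrix genes rose (median log2 0.34, adjusted p = 0.00247, adjusted p = 0.759 with an estimated correlation). Of the 44 genes 7 rose and 1 fell (7 and 1 adjusted over the list alone). Macrophage markers fell beside the matrix genes (median log2 -0.71, adjusted p = 0.00247, adjusted p = 0.759 with an estimated correlation). Of the 24 genes 1 rose and 9 fell (1 and 16 adjusted over the list alone). Antioxidant genes rose (adjusted p = 0.0414, adjusted p = 0.759 with an estimated correlation). Of the 30 genes 8 rose and 2 fell (9 and 3 adjusted over the list alone). Cell cycle genes fell (median log2 -0.50, adjusted p = 3.39e-04, adjusted p = 0.759 with an estimated correlation). Of the 17 genes 0 rose and 9 fell (0 and 11 adjusted over the list alone), with the cyclin gene Ccnb2 (-0.98 ± 0.15) and the proliferation marker Mki67 (-1.44 ± 0.25) lower. Calls of ERR targets (adjusted p = 0.430), branched-chain and ketone genes (0.450), hypertrophy genes (0.618), matrix genes (0.463), antioxidant genes (0.199) and NAD genes (0.0560) ended without Tg-Sirt1 replicate 1. Without Tg-PPARα/Tg-Sirt1 replicate 2, the list calls of ERR targets (adjusted p = 0.0601), mitochondrial dynamics (0.0516), branched-chain and ketone genes (0.0681) and antioxidant genes (0.0681) ended. Leaving out Tg-Sirt1 replicate 2 ended the list calls of mitochondrial dynamics (adjusted p = 0.0607) and macrophage markers (0.0855). Calls of branched-chain and ketone genes (adjusted p = 0.0737) and antioxidant genes (0.0598) ended without WT replicate 1 or 2. Without Tg-PPARα replicate 1 or 2, the list call of branched-chain and ketone genes (adjusted p = 0.0541) ended. Settings other than fry also ended the calls of branched-chain and ketone genes and of antioxidant genes.

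Limma called 2671 genes here, 970 higher and 1701 lower, and 453 changed at least 2-fold (221 higher, 232 lower). The share of higher genes among those called was 36.3%, and 47.5% after quantile normalization. Camera called 13 lists, 4 up and 9 down, against 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 17 by fry. Fry kept 8 of the 13, but not branched-chain and ketone genes (adjusted p = 0.0604), hypertrophy genes (0.301), matrix genes (0.331), macrophage markers (0.107) or antioxidant genes (0.147). The gene count was 1507 without Tg-Sirt1 replicate 1, 1585 without Tg-PPARα/Tg-Sirt1 replicate 1 and 788 without Tg-PPARα/Tg-Sirt1 replicate 2, and 724 genes passed in each fit that left out an array of these groups.

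The single transgenes were also compared with each other, as Tg-PPARα against Tg-Sirt1 (n = 2 arrays per group, ± SE). Acaa1b was higher in Tg-PPARα (log2 change 5.85 ± 0.26, adjusted p = 1.25e-05), as was Acta1 37.2-fold (log2 change 5.22 ± 0.35, adjusted p = 1.07e-04). Mmp12 and Egf were higher by log2 changes of 3.72 ± 0.20 and 3.63 ± 0.15. Tnnt1 was lower 42.4-fold (log2 change -5.41 ± 0.23, adjusted p = 1.07e-05), as was Endou 23.2-fold (log2 change -4.53 ± 0.26, adjusted p = 5.25e-05), and Clca4a, Ptgfr and Slc24a2 were lower by -4.36 ± 0.29, -4.27 ± 0.16 and -3.96 ± 0.13. Ppargc1a was lower in Tg-PPARα (log2 change -0.70 ± 0.14, adjusted p = 0.0163), a call that ended without Tg-Sirt1 replicate 1 (adjusted p = 0.0761) and without Tg-PPARα replicate 1 (0.107). Ppara (0.04 ± 0.17, adjusted p = 0.894), Sirt1 (-0.17 ± 0.16, adjusted p = 0.507), Esrra (-0.05 ± 0.09, adjusted p = 0.717), Esrrb (-0.36 ± 0.13, adjusted p = 0.10) and Esrrg (-0.12 ± 0.09, adjusted p = 0.394) did not pass. The sign for Ppara turned with the mean of its probe sets (-0.334) and without Tg-PPARα replicate 1 (-0.132), that for Sirt1 without the same array (0.017), and that for Esrra with quantile normalization (0.024).

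PPARα targets were higher in Tg-PPARα than in Tg-Sirt1 (median log2 0.39, adjusted p = 4.58e-13, adjusted p = 0.451 with an estimated correlation). Among 45 genes 19 were higher and 2 lower (25 and 2 adjusted over the list alone), with Pdk4 (2.60 ± 0.25) and the peroxisomal enzyme gene Hsd17b4 (1.07 ± 0.10) higher. Oxidation enzymes were higher (median log2 0.24, adjusted p = 3.99e-05, adjusted p = 0.907 with an estimated correlation). Among 20 genes 7 were higher and 0 lower (10 and 0 adjusted over the list alone). Ion channel genes were lower (median log2 -0.41, adjusted p = 1.82e-04, adjusted p = 0.382 with an estimated correlation). Among 20 genes 0 were higher and 9 lower (1 and 11 adjusted over the list alone). Nuclear receptors and coactivators were lower (adjusted p = 0.0499, adjusted p = 0.907 with an estimated correlation). Among 18 genes 0 were higher and 4 lower (0 and 6 adjusted over the list alone). Smooth muscle and pericyte markers were lower beside the ion channel genes (median log2 -0.30, adjusted p = 0.0194, adjusted p = 0.451 with an estimated correlation). Among 14 genes 0 were higher and 2 lower (0 and 2 adjusted over the list alone). Macrophage markers were lower (median log2 -0.39, adjusted p = 0.0499, adjusted p = 0.907 with an estimated correlation). Among 24 genes 1 was higher and 9 lower (1 and 9 adjusted over the list alone). Cell cycle genes were lower (median log2 -0.58, adjusted p = 0.00419, adjusted p = 0.907 with an estimated correlation). Among 17 genes 0 were higher and 5 lower (0 and 11 adjusted over the list alone), with Ccnb2 at -0.82 ± 0.15. Matrix genes did not differ past the threshold (adjusted p = 0.533), nor did complex I (adjusted p = 0.169).

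Leaving out WT replicate 1 or 2 ended the list calls of nuclear receptors (adjusted p = 0.0506) and macrophage markers (0.0506). The list call of nuclear receptors (adjusted p = 0.0643) ended without Tg-Sirt1 replicate 1. Without Tg-Sirt1 replicate 2, the list calls of nuclear receptors (adjusted p = 0.0618) and macrophage markers (0.998) ended. Leaving out Tg-PPARα replicate 2 ended the list calls of nuclear receptors (adjusted p = 0.110), smooth muscle markers (0.0518), macrophage markers (0.0517) and cell cycle genes (0.175). The list call of macrophage markers (adjusted p = 0.0556) ended without Tg-PPARα replicate 1. Without Tg-PPARα/Tg-Sirt1 replicate 1 or 2, the list call of macrophage markers (adjusted p = 0.0522) ended. Settings other than fry also ended the calls of nuclear receptors and of macrophage markers. Between the single transgenes 1824 genes passed in limma, 698 higher and 1126 lower in Tg-PPARα, and 405 differed at least 2-fold (183 higher, 222 lower). Quantile normalization moved the share of higher genes from 38.3% to 51.3%. Camera called 7 lists, 2 up and 5 down, against 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 7 by fry. Of the 7, fry kept 5, but not macrophage markers (adjusted p = 0.255) or cell cycle genes (0.161). Gene counts were 752 without Tg-PPARα replicate 1 and 1148 without Tg-PPARα replicate 2, and 1009 in a fit of these groups alone. In each fit that left out an array of these groups, 626 genes passed.

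**Figure D3:**
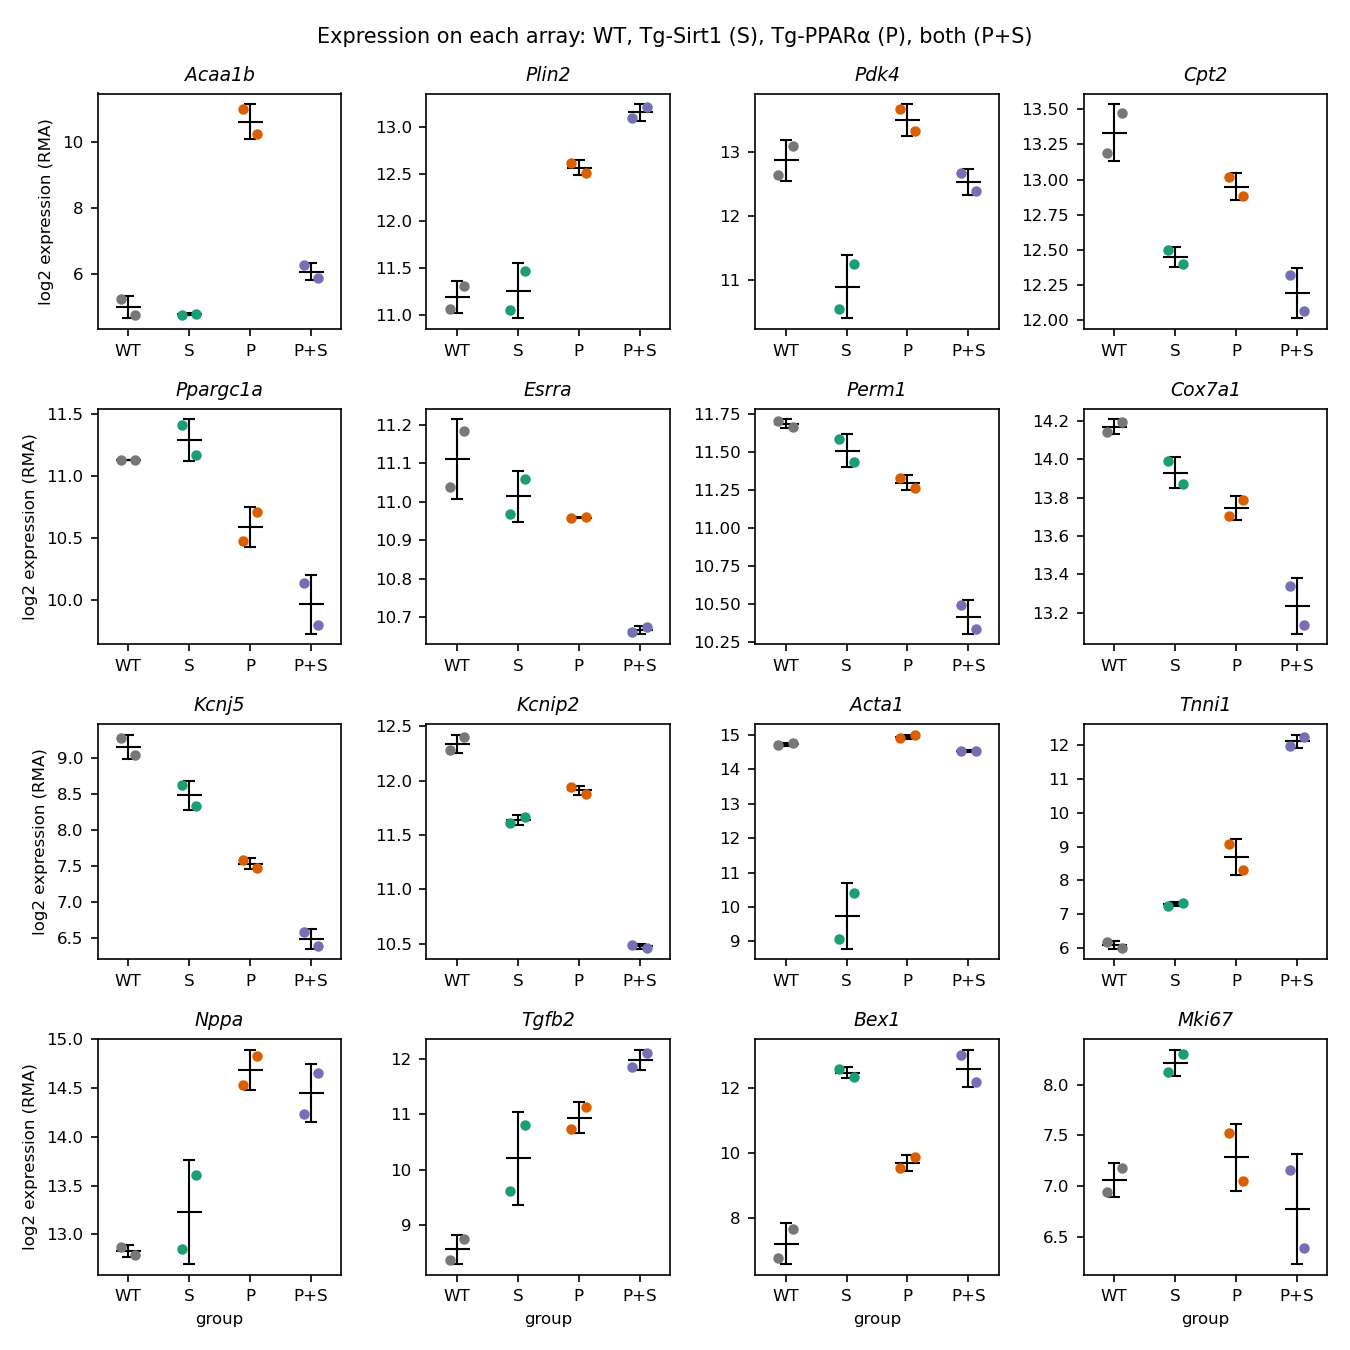
Log2 expression (vertical axis, RMA) of 16 genes in WT, Tg-Sirt1 (S), Tg-PPARα (P) and both (P+S), with 1 point per array and bars at the mean ± SD. Acta1 lay at 9.06 and 10.4 in Tg-Sirt1 and at 14.5 or more on the other arrays, and Bex1 at 6.76 and 7.64 in WT and between 9.53 and 13.0 with a transgene.

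The interaction asked for which genes the joint change departed from the sum of the single ones (log2, 2 arrays per group, ± SE). Acaa1b stood below the sum (log2 -4.34 ± 0.36, adjusted p = 0.00545), as did Mmp12 (-4.70 ± 0.29, adjusted p = 0.00179). Ptgfr, raised in Tg-Sirt1, stood below it (-3.58 ± 0.23, adjusted p = 0.00179), as did Otop1 (-2.62 ± 0.21, adjusted p = 0.00545). Ces1d, lowered by each transgene, stood above the sum (2.36 ± 0.20, adjusted p = 0.00545), as did Gm19277 (2.26 ± 0.20, adjusted p = 0.00567). Where each transgene lowered a gene, the sum may lie below the readable range, forcing a departure above it (not tested). Thbs4, raised by each transgene, stood below it (-2.29 ± 0.22, adjusted p = 0.00946). These 7 genes are among the 9 that passed in each fit without 1 array. The call of Acta1, above the sum by 4.58 ± 0.50 (adjusted p = 0.0111), ended without WT replicate 1 (adjusted p = 0.0682) or 2 (0.0986), without Tg-PPARα/Tg-Sirt1 replicate 2 (0.0602) and with a trended and robust variance model (0.0710). That of Casq1 (above by 1.98 ± 0.21, adjusted p = 0.0101) ended without Tg-PPARα/Tg-Sirt1 replicate 2 (adjusted p = 0.0602). Ppargc1a (-0.79 ± 0.20, adjusted p = 0.199), Ppara (-0.42 ± 0.23, adjusted p = 0.615), Sirt1 (-0.15 ± 0.23, adjusted p = 0.899), Esrra (-0.19 ± 0.13, adjusted p = 0.690), Esrrb (-0.29 ± 0.18, adjusted p = 0.657) and Esrrg (-0.02 ± 0.13, adjusted p = 0.981) did not pass.

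Cell cycle genes stood below the sum as a list (median log2 -0.57, adjusted p = 3.42e-08, or 0.878 with an estimated correlation). Among 17 genes 0 stood above and 0 below (0 and 4 adjusted over the list alone). Fibroblast markers stood below it (median log2 -0.46, adjusted p = 2.77e-04, or 0.878 with an estimated correlation). Among 17 genes 0 passed, also adjusted over the list alone. Matrix genes also stood below it (median log2 -0.32, adjusted p = 0.00840, or 0.950 with an estimated correlation). Among 44 genes 0 stood above and 1 below (0 and 1 adjusted over the list alone). PPARα targets stood above it as a list (median log2 0.11, adjusted p = 0.00840, or 0.950 with an estimated correlation). Among 45 genes 0 stood above and 1 below (1 and 1 adjusted over the list alone). Oxidation enzymes stood above it (median log2 0.10, adjusted p = 0.0206, or 0.950 with an estimated correlation). Among 20 genes 0 passed, also adjusted over the list alone. Skeletal muscle markers stood above the sum (median log2 0.17, adjusted p = 0.00432, or 0.840 with an estimated correlation). Among 10 genes 2 stood above and 0 below (2 and 0 adjusted over the list alone). Adipocyte markers stood above it (median log2 0.36, adjusted p = 0.0129, or 0.878 with an estimated correlation). Among 9 genes 0 passed, also adjusted over the list alone. Atrial markers stood below it (median log2 -0.64, adjusted p = 0.0129, or 0.878 with an estimated correlation). Among 11 genes 0 passed, also adjusted over the list alone. Genes of the unfolded protein response stood below it (median log2 -0.18, adjusted p = 0.0442, or 0.950 with an estimated correlation). Among 26 genes 0 passed, also adjusted over the list alone.

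Leaving out Tg-Sirt1 replicate 2 ended the list calls of PPARα targets (adjusted p = 0.0663), oxidation enzymes (0.543), matrix genes (0.940), adipocyte markers (0.0621) and unfolded protein genes (0.319). Calls of PPARα targets (adjusted p = 0.356), oxidation enzymes (0.356), matrix genes (0.0740), atrial markers (0.0740) and unfolded protein genes (0.160) ended without Tg-PPARα replicate 2. Without Tg-PPARα/Tg-Sirt1 replicate 1, the list calls of PPARα targets (adjusted p = 0.147), oxidation enzymes (0.147), matrix genes (0.120), atrial markers (0.120) and unfolded protein genes (0.149) ended. Leaving out WT replicate 1 ended the list calls of oxidation enzymes (adjusted p = 0.0575), matrix genes (0.0575) and unfolded protein genes (0.210). Calls of adipocyte markers (adjusted p = 0.0509), atrial markers (0.0745) and unfolded protein genes (0.0615) ended without WT replicate 2. Without Tg-PPARα replicate 1, the list call of unfolded protein genes (adjusted p = 0.0546) ended. Settings other than fry also ended the calls of oxidation enzymes and of unfolded protein genes. For the interaction 63 genes passed in limma, 18 above and 45 below the sum, and 56 departed at least 2-fold (17 above, 39 below). Camera called 9 lists, 4 up and 5 down, against 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (6 at an unadjusted p under 0.05). The gene count was 22 without WT replicate 1, 13 without WT replicate 2, 29 without Tg-PPARα replicate 1, 31 without Tg-PPARα replicate 2 and 17 without Tg-PPARα/Tg-Sirt1 replicate 2, and 106 with a trended and robust variance model.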

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

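Tests of all the values given here were planned; none was chosen after its result was seen. The interaction found 63 genes that departed from the sum. The departures above the sum were 4.58 for Acta1, 2.74 for Syt13, 2.36 for Ces1d, 2.26 for Gm19277, 2.22 for Tnni1, 2.09 for Psca, 2.0 for Lgi1 and 1.98 for Casq1 (log2). Those below it were -4.70 for Mmp12, -4.34 for Acaa1b, -4.05 for Tchhl1, -3.58 for Ptgfr, -3.16 for Tmprss4, -3.03 for Endou, -2.73 for Gm16316 and -2.62 for Otop1. Of these 16 genes, Ces1d, Gm19277, Mmp12, Acaa1b, Ptgfr and Otop1 kept the call without any 1 array. The others lost it in at least 1 such fit, at a highest adjusted p of 0.0986 for Acta1 and Gm16316 (without WT replicate 2), 0.0584 for Syt13 and 0.0674 for Tmprss4 (without WT replicate 2), 0.171 for Tnni1, 0.112 for Psca and 0.116 for Endou (without WT replicate 1), and 0.108 for Lgi1 and Tchhl1 and 0.0602 for Casq1 (without Tg-PPARα/Tg-Sirt1 replicate 2).

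Gene lists also departed from the sum, with adjusted p of 3.42e-08 for cell cycle genes, 2.77e-04 for fibroblast markers, 0.00432 for skeletal muscle markers, 0.00840 for PPARα targets, 0.00840 for matrix genes, 0.0129 for adipocyte markers, 0.0129 for atrial markers, 0.0206 for oxidation enzymes and 0.0442 for the unfolded protein response. None held with an estimated correlation (lowest adjusted p = 0.840). Probe sets that name no single gene are outside the comparisons: of 2679 tested, 160 passed in Tg-PPARα, 76 in Tg-Sirt1 and 555 with both transgenes, each against WT.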

How the results depend on the processing

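All alternatives reported here were planned before the results were seen; where no cause is given, the cause was not tested. Of 11816 values for 697 results on named genes, 10435 kept direction and side of the threshold, 1355 no longer passed (1061 of them among 5576 fits without 1 array), 5 newly passed and 21 changed sign. Of 1368 values for 72 list calls, 1132 were kept, 235 no longer passed (72 with an estimated correlation, 43 by fry, 91 without 1 array) and 1 changed sign. No alternative with a pseudocount was run, since the table is already on the log2 scale.

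Without 1 array at a time, the gene counts ran from 815 to 2074 for Tg-PPARα against WT, 327 to 994 for Tg-Sirt1 against WT, 2412 to 4452 for both against WT, 222 to 1110 for both against Tg-PPARα, 788 to 2338 for both against Tg-Sirt1, 752 to 1529 for Tg-PPARα against Tg-Sirt1 and 13 to 68 for the interaction. Fewer arrays leave fewer degrees of freedom. The numbers of called lists ran, in the same order, from 5 (without WT replicate 1) to 12, 8 to 17 (without Tg-Sirt1 replicate 1), 10 to 14, 4 (without Tg-PPARα replicate 1) to 11, 8 (without Tg-Sirt1 replicate 1) to 13, 3 (without Tg-PPARα replicate 2) to 10 and 4 (without Tg-PPARα replicate 2 or Tg-PPARα/Tg-Sirt1 replicate 1) to 12. Genes shared with Tg-PPARα ran from 137 to 457 for Tg-Sirt1 and from 702 to 1761 for both transgenes, and those shared by Tg-Sirt1 and both from 274 to 792. The log2 change of Ppara ran from -0.61 to -0.27 in Tg-PPARα and from -1.56 to -1.10 with both transgenes, and that of Sirt1 from -0.35 to -0.017 in Tg-Sirt1 and from -0.86 to -0.52 with both.

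With the compared groups alone, which leaves fewer arrays, 519 genes passed for Tg-Sirt1 against WT and 1009 for Tg-PPARα against Tg-Sirt1, and 220 and 419 genes were shared by Tg-Sirt1 with Tg-PPARα and with both transgenes. Every probe set by itself gave 6743 calls for both transgenes against WT, since a gene then counts more than once. The trended and robust variance model gave 106 genes in the interaction. An estimated correlation left 0 lists in each of the 7 comparisons, and fry called 3 for Tg-Sirt1 against WT, 22 for both against WT, 4 for both against Tg-PPARα and 0 for the interaction. With no filter, 13 lists passed for both against Tg-PPARα, 20 for both against Tg-Sirt1 and 11 for Tg-PPARα against Tg-Sirt1. The fall of Ppara in Tg-PPARα passed with the mean of its probe sets (-0.72) and in its other probe sets (-0.93 and -0.80).

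Whether replicate numbers pair the samples is open: deviations correlated between groups at -0.0182 to 0.368, over 0.1 in 5 of 6 pairs. With the replicate number as a block, 120 genes passed in the interaction, 4 list calls ended, and of the 697 gene results 1 newly passed, Sirt1 for both against Tg-Sirt1.

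These values changed sign. With the mean of all probe sets, Hspa8 had -0.066 in Tg-PPARα and -0.134 with both transgenes against WT, Ldb3 0.037 with both against WT, Esrrg -0.029 for both against Tg-PPARα and Ppara -0.334 for Tg-PPARα against Tg-Sirt1. In Tg-Sirt1 against WT, Esrrb had 0.0053 with median centring, and without 1 array ran from -0.128 to 0.110 (without WT replicate 2), with 0.041 without Tg-Sirt1 replicate 1. There Esrrg had -0.0077 with quantile normalization and ran from -0.044 (without WT replicate 2) to 0.106. For both against Tg-PPARα, Esrrg had -0.014 with quantile normalization and without 1 array ran from -0.014 (without Tg-PPARα/Tg-Sirt1 replicate 1) to 0.033, with -0.0048 without Tg-PPARα replicate 1. For Tg-PPARα against Tg-Sirt1, Esrra had 0.024 with quantile normalization. Without 1 array Ppara ran from -0.132 to 0.210 and Sirt1 from -0.361 to 0.017 there, with the sign turned without Tg-PPARα replicate 1, and the adjusted p of the macrophage list from 1.03e-06 to 0.998, turned without Tg-Sirt1 replicate 2. In the interaction Sirt1 ran from -0.335 to 0.043, with the sign turned without WT replicate 1 (0.022) and without Tg-PPARα replicate 2 (0.043). Esrrg ran from -0.096 to 0.054 there, turned without WT replicate 2 (0.054), Tg-Sirt1 replicate 1 (0.0012) and Tg-PPARα/Tg-Sirt1 replicate 2 (0.0024).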

Other observations

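Tests of the patterns weighed here were chosen after the results were seen, except that of bright probe sets. With both transgenes against WT (n = 2 arrays per group), the stress lists named next did not pass, while single members moved. Of apoptosis and p53 genes (5 of 24 higher and 3 lower, 5 and 3 adjusted over the list alone, adjusted p = 0.292), the survival gene Bcl2 (log2 change 1.88 ± 0.10) and the p53 target Phlda3 (2.47 ± 0.13) rose. Of autophagy genes (6 of 24 higher and 3 lower, 6 and 3 adjusted over the list alone, adjusted p = 0.293), the kinase genes Ulk1 (-0.75 ± 0.12) and Pink1 (-0.65 ± 0.11) fell. Of ubiquitin ligase genes (2 of 11 higher and 4 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.208), Trim63, which marks sarcomere proteins for breakdown (-0.88 ± 0.09), and the regulator Klf15 (-1.37 ± 0.10) fell. Heat shock genes (4 of 17 higher and 0 lower, 4 and 0 adjusted over the list alone, adjusted p = 0.473) had a median of -0.07 and a mean of 0.06, and Hsp90aa1 rose (1.57 ± 0.12). Unfolded protein genes (3 of 26 higher and 2 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.972) had a median of -0.01 and a mean of -0.04, with the camera direction up, and Herpud1 fell (-1.12 ± 0.12). The mitochondrial stress list did not pass (1 of 16 higher and 4 lower, 1 and 3 adjusted over the list alone, adjusted p = 0.536).

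Of circadian genes (2 of 17 higher and 5 lower, 2 and 8 adjusted over the list alone, adjusted p = 0.208), Cry2 (-0.93 ± 0.12) and Hlf (-1.55 ± 0.23) fell and Clock rose (0.67 ± 0.09). Of interferon genes (3 of 28 higher and 4 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.919), the GTPase gene Igtp fell (-1.20 ± 0.14) and Ifit2 rose (0.94 ± 0.10). Of adipocyte markers (2 of 9 higher and 4 lower, 2 and 4 adjusted over the list alone, adjusted p = 0.524), adiponectin, Adipoq, fell (-2.54 ± 0.32). Of epicardial markers (2 of 5 higher and 0 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.377), the keratin gene Krt18 rose (2.62 ± 0.28). Smooth muscle markers had a median of -0.12 and a mean of 0.06 (3 of 14 higher and 3 lower, 4 and 6 adjusted over the list alone, adjusted p = 0.910), and lymphocyte markers a median of 0.06 and a mean of -0.09 (2 of 11 higher and 0 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.715).

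Complex I genes fell with both transgenes (median log2 -0.36). A bias of bright probe sets is argued against: 10000 lists matched on expression had a middle median of -0.075 and a lowest of -0.30, and the share as low was 1.0e-04, the smallest they can give. Fewer cardiomyocytes in the RNA would raise markers of other cells. Endothelial markers had a median of -0.33 (95% bootstrap interval over genes, not arrays, -0.44 to -0.27) but may fall by themselves. The first test, on 14 sarcomere genes of like brightness, gave a median of -0.20 (-0.25 to 0.12). Fewer cardiomyocytes stay open, and no test here shows a change in transcription.

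Matrix genes rose with both transgenes (median log2 0.90). Macrophage markers, tested after endothelial ones, had a median of -0.61 (-0.84 to -0.22). Fewer cardiomyocytes alone would raise them, but macrophages may fall by themselves, so it stays open. More fibroblasts may account for the rise: 12 fibroblast markers outside the matrix list had a median of 0.136 (-0.19 to 0.54), and 0.45, a level of 0.5 times the matrix median, lies inside that interval. Among them Meox1 (1.71), Pcolce (0.98) and Tcf21 (0.75) rose and Fap (-0.87) fell, so cell number and expression per cell cannot be told apart.

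Genes changed at least 2-fold in Tg-Sirt1 lay side by side more often than shuffled positions allow: 10 adjacent pairs moved the same way, against a mean of 2.0 and a highest of 7 in 1000 shuffles (share 0.001, the smallest they can give). With both transgenes there were 63 pairs against WT (mean 31.2, highest 48), 20 against Tg-Sirt1 (8.37 and 18), 7 against Tg-PPARα (2.24 and 9), and in Tg-PPARα 11 (6.87 and 16). A run of 13 X-linked genes from Armcx4 to Tceal7 held 9 called higher in Tg-Sirt1 (4 without WT replicate 1), among them Bex1 (5.28), Bex4 (2.44), Tceal8 (2.10) and Bhlhb9 (1.20), and Bex1 (2.50) and Bhlhb9 (2.39) also rose in Tg-PPARα. Armcx4 (1.03) and Armcx3 (0.62), higher in Tg-Sirt1, did not pass with both transgenes (-0.38 and 0.04); without WT replicate 1 their Tg-Sirt1 calls ended (adjusted p = 0.0836 and 0.0840), as did that of Bex4 (0.0754), and without WT replicate 2 that of Armcx3 (0.0904). Related genes that lie together stay open: without pairs alike in the first 3 letters of their names 8 remained (share 0.001), and 4 (share 0.112) once the families of that run, chosen after the pairs were seen, counted as 1, which set that number; with both transgenes 53 then remained against WT (mean 30.1, highest 48) and 15 against Tg-Sirt1 (share 0.0180).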
